A study of Mus musculus with 12 samples.

How the data were processed

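Total RNA of gastrocnemius from 12 mice, 3 in each of 4 shRNA groups, had been hybridised to 1-colour Affymetrix arrays with biotin label, per the labels' protocols. The deposited table held log2 levels of 25206 probe sets on all 12 arrays, between 4.78 and 14.09. The authors made these log2 values with RMA, per the submitters' processing notes, a method that corrects background, normalizes arrays to equal distributions and summarises the probes of a set on the log2 scale. The version of RMA, the probe set definitions and the genome build are not given in the sources used here. Of the 12 deposited columns 11 held the same values in a different order, and the first, of control animal 18, departed from them by at most 0.00187. Because the distributions were made equal, a change of most transcripts in one direction would not be visible. Array medians differed by little for the same reason, and the correlation between arrays lay between 0.990 and 0.998.

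Probe sets carry a gene identifier, and 23185 of them were given 1 gene symbol through the annotation table supplied with the arrays. The other 2021 (8.02%) had no single symbol and entered only an alternative with all probe sets. Every named gene had 1 probe set, so no choice among probe sets was needed. No filter on dim probe sets and no pseudocount were applied. Groups came from the submitters' labels. Animal numbers differ between groups and pair no samples. No batch, date or slide is given in the sources used here, so a batch that follows the groups would not be seen.

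All genes were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, over all 12 arrays with 4 group means, without trend or robust options. The fit had 8 residual and 1.69 prior degrees of freedom. There were 6 comparisons: each of the 3 shRNA groups against control, the group with both viruses against each single group, and the interaction, which is the difference of TSC22D4+LCN13 and LCN13 shRNA minus the difference of TSC22D4 shRNA and control. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over 23185 genes within a comparison, and a gene passed at an adjusted p below 0.05. Changes are differences of mean log2 level with the moderated standard error.

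The groups, the tests, the alternative settings, the rule for named genes and 48 gene lists were fixed before the data were examined. The lists cover metabolic and signalling pathways of muscle, stress and immune responses, fibre types and markers of other cell types that a calf muscle sample can hold. Each list with at least 5 measured members was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 48 lists. The tests were repeated with an estimated correlation and with fry, which asks whether a list moves on balance one way without setting it against other genes. With an estimated correlation the call of 1 list in 1 comparison held, that of the interferon response for LCN13 shRNA against control. Named genes were the 2 targets, the 12 largest rises and 12 largest falls past the threshold, up to 4 members of a list past its threshold and up to 2 of another list, and where fewer than 10 genes passed, those with the smallest p up to 10. Predicted and unnamed genes were left out, and the text names a subset of these genes. A list score of an array is the mean deviation of its members from their 12-array means.

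The same steps were tested on simulated data, with 23185 genes drawn from the real levels and spreads and 200 of them changed. In the simulated comparison of TSC22D4 shRNA with control, 86.6% of genes changed by 0.5 on the log2 scale were called, 98.5% at 1 and 100% at 2. For LCN13 shRNA against control the shares were 82.1%, 98.5% and 100%, and for TSC22D4+LCN13 shRNA against control 89.6%, 95.5% and 100%. For TSC22D4+LCN13 against TSC22D4 shRNA they were 80.6%, 100% and 100%, against LCN13 shRNA 80.6%, 95.5% and 100%, and for the interaction 67.2%, 91% and 97%. The 200 changed genes were drawn from all genes at any level, so these shares do not carry over to genes with a large spread. Between 12 and 17 unchanged genes were called in a comparison. A list of 30 genes shifted by 0.5 was called in each comparison, and 0 of 48 unshifted lists were. The simulated arrays and genes were drawn independently and do not hold differences in sample composition. Genes of a list therefore did not vary together there. For this reason the simulation cannot show how often camera calls unchanged lists in real arrays.

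Alternatives were all probe sets, the mean of the probe sets of a gene, genes above the median level, eBayes with trend and robust options, quantile normalization, centring of each array on its median, array weights, the arrays of the compared groups alone, average effects over both backgrounds (6 arrays against 6), and each array left out in turn. After the data were seen 3 more were added: a score of 6 tendon genes (Tnmd, Scx, Fmod, Comp, Cilp2 and Chad) as a covariate, the hepatocyte list score as a covariate, and the data without animals 22, 23 and 30 together. The last left LCN13 animal 21 as the only array of its group, so no counts of passing genes or lists are given. Overlaps between comparisons with the same controls were set beside 50 simulations in which all 12 arrays were drawn without group differences, each gene independently. Shared genes were counted past the threshold and with as many top-ranked genes as were called. No measure of detection above background was used. Counts of passing genes and lists were also made for other splits of the same arrays.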

Results

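Gene expression was measured on 12 microarrays of gastrocnemius, the large calf muscle, from 12-week-old db/db mice on the BKS background, which lack a functional leptin receptor and become obese and diabetic. Each animal had received adenovirus coding for short hairpin RNA (shRNA), a construct that directs degradation of a target transcript, and was killed 1 week later. The targets were TSC22D4, a transcriptional regulator of the TSC22 leucine zipper family, and LCN13, a secreted lipocalin. Each group received the same total number of plaque-forming units of virus. Control animals received control shRNA virus alone, both single-target groups received the named virus and control virus in equal parts, and the group with both targets received the 2 target viruses in equal parts with no control virus. Of 7 animals treated per group, 3 were placed on arrays: control animals 18, 19 and 20, LCN13 animals 21, 22 and 23, TSC22D4 animals 25, 26 and 27, and TSC22D4+LCN13 animals 29, 30 and 32. Each array came from a separately numbered animal. The labels call the chosen animals representative of their groups, so the spread between arrays may be smaller than that between all treated animals. The deposited values were log2 levels of 23185 named genes, and the number of arrays limits the precision.

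The targeted transcripts were examined first, in all 12 arrays. Tsc22d4 lay between 6.43 and 7.01 on the log2 scale, at the 68.3rd to 74.2nd percentile of the genes of its array. It was not lower in the arrays labelled TSC22D4 shRNA than in control, with a log2 difference of 0.24 (SE 0.121, limma adjusted p = 0.619, 3 arrays against 3). In the arrays labelled TSC22D4+LCN13 shRNA the difference from control was 0.23 (adjusted p = 0.337), and in those labelled LCN13 shRNA it was 0.22 (adjusted p = 0.512). Obp2a, the current symbol of Lcn13, lay between 4.90 and 4.97 in all 12 arrays, at the 5.4th to 12.3rd percentile, against a lowest value of 4.78 for any probe set. A level this close to the floor of the array allows no statement on its knockdown. Tsc22d4 RNA was thus not measurably lower in muscle, the knockdown of LCN13 could not be assessed, and the groups are named below by their labels. The differences below follow the virus given and are not shown to come from knockdown within muscle, since the tissue reached by the virus is not given in the sources used here. The liver and abdominal fat of these animals, collected in the same experiment, were not analysed here.

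The comparison of TSC22D4 shRNA with control asks which muscle transcripts changed after TSC22D4 virus. Interferon-induced genes held the largest changes, which were falls. Ifit1, an antiviral RNA-binding protein, fell by 2.96 on the log2 scale (SE 0.175, adjusted p = 0.000122), which is 7.81-fold lower. It measured 9.61 ± 0.287 (SD, n = 3) in control arrays and 6.65 ± 0.142 (SD, n = 3) in TSC22D4 arrays. Irf7, a transcription factor that drives interferon production, was 6.27-fold lower (log2 change -2.65, SE 0.196, adjusted p = 0.000343). The smallest adjusted p belonged to Herc6, the mouse ligase that attaches the ubiquitin-like protein ISG15 (log2 change -1.78, SE 0.074, adjusted p = 1.35e-05). Cmpk2, a mitochondrial nucleotide kinase, Oasl2 and Oas2, of the oligoadenylate synthetase family, Ifit2 and the viral RNA sensor Ddx58 fell by 2.24, 2.07, 1.91, 1.87 and 1.51 on the log2 scale.

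Of the 34 measured members of the interferon response list, 14 fell and 20 did not pass, with a median log2 change of -0.46 over the list. Adjusted over the list alone, 24 members were lower and 1 was higher. The list lay below the other genes by limma's camera test (adjusted p = 1.7e-37), with adjusted p = 0.0587 with an estimated correlation, so that this call was lost there. By fry, which tests the list on its own, the adjusted p was 0.00045. Rises were small. Ppt1, a lysosomal thioesterase, rose by 0.47 (SE 0.0391, adjusted p = 0.000805), Mrps18b, of the mitochondrial ribosome, by 0.33 (SE 0.0497, adjusted p = 0.0285), and Copz2, a subunit of the COPI vesicle coat, by 0.29 (SE 0.0397, adjusted p = 0.0147).

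Of the following lists no member passed over all genes in this comparison. The extracellular matrix list had a median log2 change of 0.29 over 33 members (adjusted p = 0.702 with an estimated correlation), with 1 member higher when adjusted over the list alone. The list of fibroblasts and tendon cells had a median of 0.32 over 20 members (adjusted p = 0.702 with an estimated correlation), with 0 members past when adjusted over the list alone. Col1a1, a chain of type I collagen, was 1.25 higher on the log2 scale (SE 0.462, adjusted p = 0.428) and Tnmd, a tendon membrane protein, 1.16 higher (SE 0.411, adjusted p = 0.405), and neither passed. A score of 6 tendon genes ranged from -1.06 to 0.11 over the control arrays and from -0.37 to 0.31 over the TSC22D4 arrays, and with it as a covariate the adjusted p of the matrix list, which holds none of the 6, was 0.981. Glucocorticoid targets had a median of -0.21 over 25 members (adjusted p = 0.656 with an estimated correlation), 2 of them lower when adjusted over the list alone. Among these Ddit4, a stress-induced inhibitor of mTORC1, measured -1.47 (SE 0.351, adjusted p = 0.16) and did not pass. Ribosomal protein genes had a median of -0.084 over 28 members (adjusted p = 0.0587 with an estimated correlation, fry adjusted p = 0.016), 3 of them lower when adjusted over the list alone. Oxidative phosphorylation had a median of 0.023 over 38 members (adjusted p = 0.702 with an estimated correlation), with 6 members higher when adjusted over the list alone. Its camera call was lost without control animal 18 (adjusted p = 0.576). Insulin signalling and glucose uptake did not pass (median -0.07 over 23 members, adjusted p = 0.375).

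In total 78 genes passed an adjusted p of 0.05 in limma, 12 higher and 66 lower, and 25 of those lower differed by over 2-fold. The count fell to 33 when limma was given these 6 arrays alone and to 25 with the tendon score as a covariate, a setting added after the data were seen. Leaving out control animal 20 gave 49 genes, and leaving out TSC22D4 animals 25, 26 or 27 gave 36, 38 or 48. Camera called 14 of 48 lists, 8 higher and 6 lower, against 9 without control animal 18 and 0 with an estimated correlation. Ifit1, Irf7, Cmpk2, Oasl2, Oas2, Ifit2, Herc6, Ddx58 and Ppt1 passed in each of the 12 fits that left out 1 array. Mrps18b was lost in 7 of them (largest adjusted p = 0.113, without control animal 20) and Copz2 in 3 (largest adjusted p = 0.0856, without TSC22D4 animal 26).

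**Figure D1:**
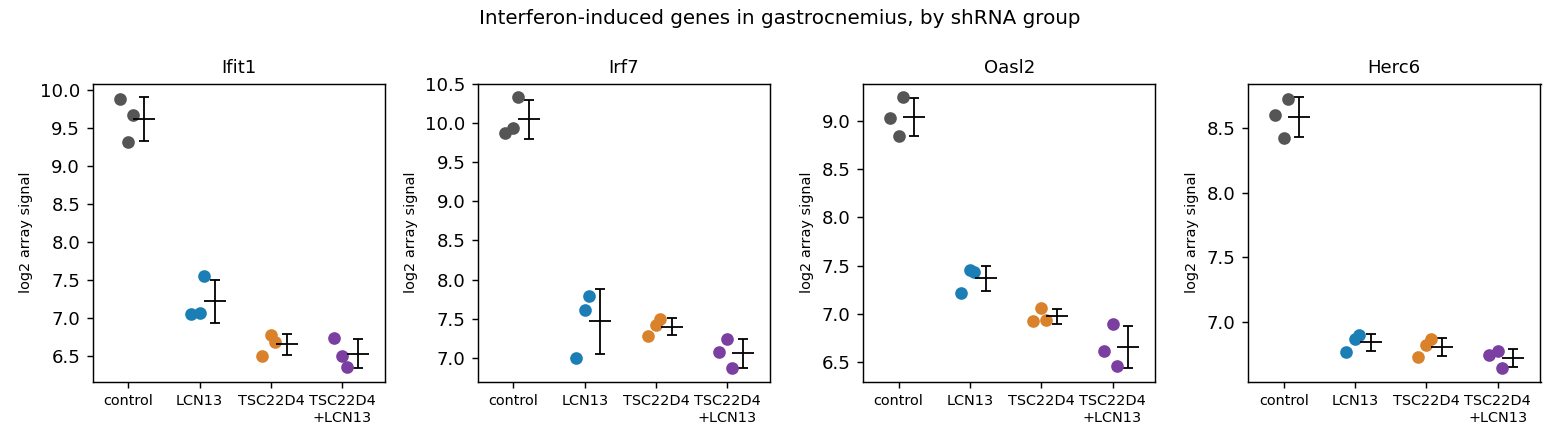
Log2 array signal (vertical axis) of Ifit1, Irf7, Oasl2 and Herc6 in each of the 12 arrays, by shRNA group (horizontal axis), with 1 point per animal and the mean ± SD of 3 arrays beside the points. The 3 control arrays lay between 9.31 and 9.88 for Ifit1, and the other 9 arrays lay between 6.35 and 7.54.

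The comparison of LCN13 shRNA with control asks the same of LCN13 virus. Interferon-induced genes again held the largest falls. Irf7 fell by 2.58 (SE 0.196, adjusted p = 0.00047) and Ifit1 by 2.40 (SE 0.175, adjusted p = 0.00047) on the log2 scale, or 5.98-fold and 5.28-fold. Cmpk2, Oas2, Herc6, Oasl2 and Ifit2 changed by -2.04, -1.81, -1.74, -1.67 and -1.66. Rises were again smaller: Nceh1, a hydrolase of neutral cholesterol esters, rose by 0.65 (SE 0.0903, adjusted p = 0.0129) and Tmem47, a membrane protein of cell junctions, by 0.63 (SE 0.0806, adjusted p = 0.0103). Of the 34 measured interferon response genes, 22 fell and 12 did not pass, with a median of -0.72, and 30 were lower when adjusted over the list alone. This list passed camera (adjusted p = 3.3e-46) and kept its call, with adjusted p = 0.0357 with an estimated correlation and a fry adjusted p of 0.00014. The number of its members that fell was 13 without control animal 20, 14 without LCN13 animal 21 and 13 without LCN13 animal 23. It was 2 when limma was given these 6 arrays alone and 6 with the tendon score as a covariate. With that covariate the list's median was still -0.54, 33 of 34 members were below 0 and the camera adjusted p was 2.28e-39, while the median SE of its genes went from 0.126 to 0.157 and the residual degrees of freedom from 8 to 7.

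Trim63, the ubiquitin ligase MuRF1 of muscle wasting, fell by 0.75 (SE 0.12, adjusted p = 0.0251), and Klf15, a transcription factor induced by glucocorticoids, fell by 0.68 (SE 0.104, adjusted p = 0.022). Cebpd, another glucocorticoid-induced transcription factor, fell by 0.58 (SE 0.0947, adjusted p = 0.0276) to 5.32, a level not shown to lie above background. Fbxo32, the ubiquitin ligase atrogin-1, measured -0.58 (SE 0.192, adjusted p = 0.224) and did not pass. Of 25 glucocorticoid targets, 4 fell, with a median of -0.21 and 7 lower when adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). Of 20 genes of muscle atrophy, 2 fell, with a median of -0.11 and 4 lower when adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). Branched-chain amino acid catabolism had 2 of 20 members lower, a median of -0.17 and 7 lower when adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). Its Bckdha and Bckdhb, subunits of the dehydrogenase that commits these amino acids to breakdown, measured -0.53 (adjusted p = 0.103) and -0.47 (adjusted p = 0.0796) and did not pass. In the proteasome list 1 of 29 members fell, with a median of -0.12 and 7 lower when adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). FoxO targets had 2 of 24 members lower, a median of -0.092 and 7 lower when adjusted over the list alone (adjusted p = 0.516 with an estimated correlation), and their camera call was lost without control animal 18 (adjusted p = 0.135).

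Fatty acid oxidation and PPAR targets had 2 of 25 members higher, a median of 0.14 and 4 higher when adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). The camera call of this list was also lost with the hepatocyte score as a covariate (adjusted p = 0.0562) and was kept with the tendon score (adjusted p = 8.77e-09). Both settings were added after the data were seen. Cd36, a fatty acid transporter, rose by 0.30 (SE 0.043, adjusted p = 0.0151), and Acot2, a mitochondrial acyl-CoA thioesterase, by 0.84 (SE 0.151, adjusted p = 0.0386). Cd36 was lost in 3 of the 12 fits that left out 1 array (largest adjusted p = 0.0637, without LCN13 animal 21) and Acot2 in 10 (largest adjusted p = 0.11, without LCN13 animal 23). Trim63 was lost in 4 (largest adjusted p = 0.0655, without LCN13 animal 21), Klf15 in 3 (largest adjusted p = 0.0893, without control animal 20) and Cebpd in 5 (largest adjusted p = 0.0913, without LCN13 animal 21). Insulin signalling and glucose uptake had 1 of 23 members lower and did not pass as a list (median -0.028, adjusted p = 0.233).

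No member of the connective tissue and hepatocyte lists passed over all genes in this comparison. The extracellular matrix list had a median of 0.40 over 33 members, 2 of them higher when adjusted over the list alone (adjusted p = 0.509 with an estimated correlation). Fibroblast and tendon cell genes had a median of 0.63 over 20 members, 9 of them higher when adjusted over the list alone (adjusted p = 0.39 with an estimated correlation). Postn, a matrix protein of tendon and injured tissue, measured 1.38 (SE 0.316, adjusted p = 0.0925), and Tnmd 1.65 (SE 0.411, adjusted p = 0.113). The tendon score ranged from 0.14 to 0.44 over the LCN13 arrays, against -1.06 to 0.11 over the control arrays, and with it as a covariate the adjusted p of the matrix list was 0.761. Hepatocyte markers had a median of 0.33 over 22 members, with 0 past when adjusted over the list alone (adjusted p = 0.58 with an estimated correlation), and the camera call was lost without LCN13 animal 22 (adjusted p = 0.062). Alb, the liver's main plasma protein, measured 1.70 with an SE of 1.08 (adjusted p = 0.615), and its levels were 9.07, 11.6 and 10.9 in animals 21, 22 and 23. The hepatocyte score was high in animals 22 (0.873) and 23 (0.35) but not in animal 21 (-0.132), which lay below control animals 19 (-0.001) and 20 (-0.057).

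For LCN13 shRNA against control 197 genes passed in limma, 55 higher and 142 lower, with 1 higher and 31 lower by over 2-fold. The count was 18 when limma was given these 6 arrays alone and 20 with the tendon score as a covariate, a setting added after the data were seen. It fell to 77 without control animal 20, to 86 and 101 without LCN13 animals 21 and 23, and to 127 and 120 without TSC22D4 animals 26 and 27, which enter through the shared estimate of the spread. Camera called 13 of 48 lists, 6 higher and 7 lower, against 1 with an estimated correlation. Ifit1, Irf7, Cmpk2, Oas2, Herc6, Oasl2, Ifit2, Nceh1 and Tmem47 passed in each of the 12 fits that left out 1 array.

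The comparison of TSC22D4+LCN13 shRNA with control asks what changed when both viruses were given together. Interferon-induced genes held the largest falls here too. Ifit1 fell by 3.09 (SE 0.175, adjusted p = 6.4e-05), or 8.50-fold, from 9.61 ± 0.287 (SD, n = 3) to 6.53 ± 0.192 (SD, n = 3). Irf7 was 7.92-fold lower (SE 0.196, adjusted p = 0.000147), and Oasl2, Oas2, Cmpk2, Herc6, Rnf213 and the viral RNA sensor Ifih1 changed by -2.38, -2.18, -2.11, -1.86, -1.82 and -1.49. Of the 34 interferon response genes, 20 fell and 14 did not pass, with a median of -0.56, and 26 were lower and 1 higher when adjusted over the list alone. The list passed camera (adjusted p = 5.6e-22), with adjusted p = 0.22 with an estimated correlation and a fry adjusted p of 0.00025. The number of members that fell was 12 with these 6 arrays alone and 8 with the tendon score as a covariate. With the covariate the list's median was -0.44, 28 of 34 members were below 0 and the camera adjusted p was 2.05e-15, with a median SE of 0.161 against 0.126 without it.

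Here 20 of the genes past the threshold were higher by over 2-fold, and 106 of all that passed had a mean level below the array median. The median of an array was 5.45. Actc1, the cardiac form of alpha-actin, rose by 1.41 (SE 0.174, adjusted p = 0.00413), Tceal7 by 1.38 (SE 0.189, adjusted p = 0.00641) and Mki67, a marker of dividing cells, by 0.32 (SE 0.0473, adjusted p = 0.00903), and all 3 passed in each of the 12 fits that left out 1 array. Mki67 measured 5.23 in control and 5.55 in these arrays, a level not shown to lie above background. Hbb-b1, a beta-globin, rose by 1.87 (SE 0.397, adjusted p = 0.0329), from 5.32 ± 0.468 (SD, n = 3) to 7.19 ± 0.834 (SD, n = 3), with a control level likewise not shown to lie above background, and Alas2, the first enzyme of haem synthesis in red cell precursors, by 1.42 (SE 0.339, adjusted p = 0.048). These were the 2 of 8 red cell markers that rose, with a median of 0.16 over the list and 3 higher when adjusted over the list alone (adjusted p = 0.601 with an estimated correlation), and the list passed camera in 9 of the 12 fits that left out 1 array (largest adjusted p = 0.115, without TSC22D4+LCN13 animal 29). Of 21 macrophage and monocyte markers 3 rose, with a median of 0.21, and 5 were higher and 3 lower when adjusted over the list alone (adjusted p = 0.73 with an estimated correlation). Among them Mrc1, the mannose receptor of tissue macrophages, rose by 0.81 (SE 0.149, adjusted p = 0.02), and the list passed camera in 9 of the 12 fits (largest adjusted p = 0.581, without TSC22D4+LCN13 animal 30). The camera adjusted p of that list was 0.34 with the tendon score and 0.0746 with the hepatocyte score as a covariate. That of the red cell list was 0.00256 with the tendon score and 0.0746 with the hepatocyte score. The cell cycle list, several of whose members lay near the floor of the array, had 2 of 29 members higher, a median of 0.066, and 6 higher and 3 lower when adjusted over the list alone (adjusted p = 0.22 with an estimated correlation, fry adjusted p = 0.0222). Ribosomal protein genes had 3 of 28 members lower, a median of -0.078 and 4 lower when adjusted over the list alone (adjusted p = 0.22 with an estimated correlation, 0.161 with the tendon score and 0.0198 with the hepatocyte score as a covariate, fry adjusted p = 0.00877).

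The medians of the connective tissue lists were above 0. Of 33 extracellular matrix genes 5 rose, with a median of 0.54 and 18 higher when adjusted over the list alone (adjusted p = 0.601 with an estimated correlation). Of 20 fibroblast and tendon cell genes 3 rose, with a median of 0.64 and 12 higher when adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). Mfap4, a microfibril protein, rose by 2.02 (SE 0.454, adjusted p = 0.0393) and Postn was 2.83-fold higher (SE 0.316 on the log2 scale, adjusted p = 0.0323). Col1a1 measured 1.62 (SE 0.462, adjusted p = 0.0814) and Tnmd 1.66 (SE 0.411, adjusted p = 0.0541), and neither passed. The tendon score ranged from 0.049 to 0.48 over these arrays, and with it as a covariate the matrix median was 0.11 and 0 of the 33 genes passed in limma. Mfap4 was lost in 8 and Postn in 5 of the 12 fits that left out 1 array, Hbb-b1 in 4 and Alas2 in 9, each with its largest adjusted p without control animal 20 (0.122, 0.106, 0.107 and 0.135). Mrc1 was lost in 3 (largest adjusted p = 0.0575, without control animal 19).

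A total of 1007 genes passed for TSC22D4+LCN13 shRNA against control in limma, 399 higher and 608 lower, most by little, with a median size of 0.32 on the log2 scale. The count was 124 with these 6 arrays alone and 34 with the tendon score as a covariate. It fell to 478, 531 and 334 without control animals 18, 19 and 20 and to 470 without TSC22D4+LCN13 animal 32. Camera called 10 of 48 lists, 8 higher and 2 lower, against 6, 5 and 17 without control animal 18 and TSC22D4+LCN13 animals 30 and 32, and 0 with an estimated correlation. Insulin signalling and glucose uptake did not pass, with 0 of 23 members changed (median -0.06, adjusted p = 0.105).

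The lists of genes that differed from control overlapped. TSC22D4 and LCN13 shRNA shared 54 lower genes, where independent lists would share 0.4, and 5 higher genes, where they would share 0.03. TSC22D4 and TSC22D4+LCN13 shRNA shared 65 lower and 11 higher genes, against 1.73 and 0.21 for independent lists. LCN13 and TSC22D4+LCN13 shRNA shared 89 lower and 27 higher genes, against 3.72 and 0.95. All 3 comparisons had 54 lower genes in common, 14 of them in the interferon response list. That list does not hold every interferon-induced gene, and Cmpk2, Herc6, Parp14 and Rnf213 outside it were also among the 54. The 3 comparisons also shared 5 higher genes, which were Dhx57, Ppt1, Ggcx, Copz2 and Smim20. Dhx57 and Smim20 were chosen after their values were seen. In 50 simulations of unchanged groups against 1 set of 3 controls the number shared past the threshold was 0, because almost no gene passes there. With as many top-ranked genes taken as were called, the simulations shared up to 25, 38 and 66 lower genes in these 3 pairs and 19 in all 3 comparisons, below the observed numbers. They shared up to 7, 11 and 31 higher genes in the pairs and 6 in all 3 comparisons, so that the sharing of higher genes was within what shared controls give. Each gene was drawn on its own in these simulations, whereas genes regulated together would be shared as a block. The simulated numbers are therefore no upper bound on the sharing of lower genes through shared controls. Because the same 3 control arrays stand in all 3 comparisons and cannot be split into sets of 2, how much of the excess comes from the shared controls cannot be told.

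Comparing TSC22D4+LCN13 with TSC22D4 shRNA asks what changed when LCN13 virus took the place of the control virus given with TSC22D4 virus. By limma 0 genes passed, while 2434 of 23185 had an unadjusted p under 0.05. A share of 0.05 of the genes falls under that level on average when no gene differs. The smallest adjusted p was 0.0788, for Alg12, a mannosyltransferase of protein glycosylation, at a log2 difference of 0.37 (SE 0.039). No other tool was run on single genes. Ppm1k, the phosphatase that activates branched-chain amino acid breakdown, measured -0.70 (SE 0.0973), Bmp4, a growth factor, 0.43 (SE 0.0621), and Timp1, an inhibitor of matrix proteases, 0.42 (SE 0.0637), each at an adjusted p of 0.136. Timp1 measured 5.42 in the TSC22D4 arrays, a level not shown to lie above background. Leaving out control animal 18 gave 2 genes, leaving out TSC22D4+LCN13 animal 30 gave 1, and the hepatocyte score as a covariate, added after the data were seen, gave 2.

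At the level of lists, camera called 14 of 48 for this comparison, 11 higher and 3 lower, against 0 with an estimated correlation and 0 by fry. Branched-chain amino acid catabolism was called lower (median -0.16 over 20 members, 0 past over all genes, 2 lower when adjusted over the list alone, adjusted p = 0.593 with an estimated correlation). Against control its median was 0.074 with TSC22D4 shRNA, where camera called it higher (adjusted p = 0.00594, 0.702 with an estimated correlation). That call was lost without TSC22D4 animal 25 (camera adjusted p = 0.111). With TSC22D4+LCN13 shRNA the median against control was -0.14 and the list did not pass (adjusted p = 0.0672). The cell cycle list was called higher (median 0.057 over 29 members, 0 past over all genes, 2 higher when adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Members such as Cdk1 (5.09 and 5.23), Top2a (5.15 and 5.25) and Nusap1 (5.14 and 5.25 in the TSC22D4 and TSC22D4+LCN13 arrays) lay below the array median of 5.45 and were not shown to lie above background, while Cdc20 (5.85 and 5.77) and E2f1 (5.58 and 5.56) were not higher. For TSC22D4+LCN13 against TSC22D4 shRNA these 2 lists passed camera in each of the 12 fits that left out 1 array. Adipocyte markers (median 0.30 over 18 members, adjusted p = 0.593 with an estimated correlation) lost their camera call without TSC22D4+LCN13 animal 30 (adjusted p = 0.608). The extracellular matrix list (median 0.19 over 33 members, adjusted p = 0.62 with an estimated correlation) passed camera in 10 of the 12 fits, with its largest adjusted p of 0.354 without animal 30, and had an adjusted p of 0.185 with the tendon score as a covariate. Without that animal 3 lists were called, and without TSC22D4 animal 25 there were 9. Insulin signalling and glucose uptake did not pass (median -0.04 over 23 members, adjusted p = 0.278).

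Comparing TSC22D4+LCN13 with LCN13 shRNA asks what changed when TSC22D4 virus took the place of the control virus given with LCN13 virus. Hbb-b1 rose by 1.98 (SE 0.397, adjusted p = 0.029), Alas2 by 1.57 (SE 0.339, adjusted p = 0.0357) and Slc4a1, the anion exchanger of the red cell membrane, by 0.63 (SE 0.123, adjusted p = 0.0268). In the LCN13 arrays Hbb-b1 measured 5.22 and Slc4a1 5.17, levels not shown to lie above background. Tent5c, a poly(A) polymerase, rose by 1.66 (SE 0.274, adjusted p = 0.0145). Hbb-b1, Alas2 and Slc4a1 were the 3 of 8 red cell markers that rose, with a median of 0.32 over the list and 5 higher when adjusted over the list alone (adjusted p = 0.869 with an estimated correlation). A pair of interferon-induced genes, Igtp and Isg20, rose by 1.23 (SE 0.21, adjusted p = 0.0168) and 0.93 (SE 0.124, adjusted p = 0.00785), while the interferon response list as a whole did not pass (3 of 34 higher, 1 lower, median -0.0033, adjusted p = 0.612). Trim63 rose by 0.62 (SE 0.12, adjusted p = 0.0261), Actc1 by 1.12 (SE 0.174, adjusted p = 0.0114) and Cbr2, a carbonyl reductase, by 0.98 (SE 0.138, adjusted p = 0.00892).

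Snora16a fell by 2.00 (SE 0.416, adjusted p = 0.0319), Snord13 by 1.52 (SE 0.299, adjusted p = 0.027) and Snora17 by 1.48 (SE 0.258, adjusted p = 0.0177). Snord13 measured 5.30 in TSC22D4+LCN13 and 5.18 in TSC22D4 arrays, levels not shown to lie above background. Each of these 3 small nucleolar RNA genes was also below control with TSC22D4 shRNA without passing, with Snora16a at -1.70 (adjusted p = 0.171), Snora17 at -1.21 (adjusted p = 0.116) and Snord13 at -0.54 (adjusted p = 0.667). By these values Snord13 stood higher in the LCN13 arrays than in control, and most of its difference of 1.52 came from that. Of 641 small RNA genes, a class formed after the data were seen, 23 were lower (3.59%), against 637 of 22207 other genes (2.87%), and the difference was not tested. Bhmt, a liver enzyme of methionine synthesis, fell by 0.88 (SE 0.121, adjusted p = 0.0082). Hepatocyte markers had a median of -0.25 over 22 members with 0 past when adjusted over the list alone (adjusted p = 0.869 with an estimated correlation), and Alb measured -1.83 with an SE of 1.08 (adjusted p = 0.384). That list passed camera in 9 of the 12 fits that left out 1 array (largest adjusted p = 0.627, without LCN13 animal 22). Macrophage and monocyte markers had 2 of 21 members higher, a median of 0.21 and 6 higher when adjusted over the list alone (adjusted p = 0.869 with an estimated correlation), and lost their call without TSC22D4+LCN13 animal 30 (adjusted p = 0.171).

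In this comparison 977 genes passed in limma, 305 higher and 672 lower, of which 8 higher and 4 lower differed by over 2-fold. With these 6 arrays alone limma called 0 genes, so that the count rests on the spread estimated from all 12 arrays. It was 543 with array weights, 318, 567 and 563 without LCN13 animals 21, 22 and 23, and 468 and 391 without TSC22D4+LCN13 animals 29 and 32. Camera called 6 of 48 lists, 5 higher and 1 lower, against 3 without TSC22D4+LCN13 animal 30, 3 without animal 32 and 0 with an estimated correlation. Tent5c, Actc1, Isg20, Cbr2 and Bhmt passed in each of the 12 fits that left out 1 array. Hbb-b1 was lost in 5 of them (largest adjusted p = 0.0781, without LCN13 animal 21), Alas2 in 7 (0.101, without LCN13 animal 21), Slc4a1 in 4 (0.0669, without LCN13 animal 22), Snora16a in 5 (0.0957, without LCN13 animal 21), Snord13 in 4 (0.0761, without TSC22D4+LCN13 animal 32), Snora17 in 2 (0.0547, without TSC22D4+LCN13 animal 29), Trim63 in 3 (0.066, without TSC22D4+LCN13 animal 32) and Igtp in 1 (0.0507, without TSC22D4+LCN13 animal 29).

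**Figure D2:**
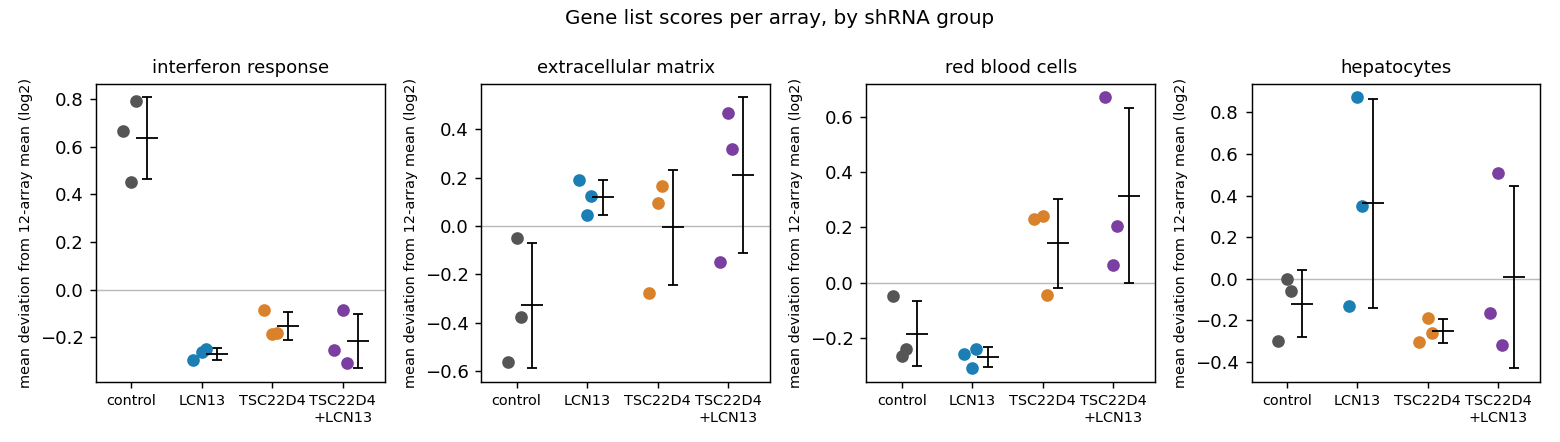
Mean deviation from the 12-array mean, in log2 units (vertical axis), over the genes of 4 lists (interferon response, extracellular matrix, red blood cells and hepatocytes), with 1 point per array by shRNA group (horizontal axis) and the mean ± SD of 3 arrays beside the points. The interferon score lay between 0.45 and 0.79 in the control arrays and between -0.31 and -0.08 in the other 9, while the hepatocyte score reached 0.87 in LCN13 animal 22 and 0.51 in TSC22D4+LCN13 animal 30.

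The interaction asks whether the change with TSC22D4 virus differed between animals with and without LCN13 virus. It did so for interferon-induced genes. They fell where TSC22D4 virus took the place of part of the control virus in animals without LCN13 virus. They changed less where it took the place of the control virus given with LCN13 virus. There Oasl2 still fell by 0.71 (SE 0.126, adjusted p = 0.0186) and Ifit1 measured -0.69 (SE 0.175, adjusted p = 0.0585). Herc6 had an interaction of 1.66 on the log2 scale (SE 0.105, adjusted p = 0.000697), with means of 8.59 in control, 6.81 in TSC22D4, 6.84 in LCN13 and 6.72 in TSC22D4+LCN13 arrays. Ifit1 had 2.28 (SE 0.248, adjusted p = 0.0161), Cmpk2 2.18 (SE 0.24, adjusted p = 0.0161), Irf7 2.24 (SE 0.277, adjusted p = 0.0229) and Parp14, an interferon-induced ADP-ribosyltransferase, 1.33 (SE 0.13, adjusted p = 0.011). Of the 34 interferon response genes 7 had a positive interaction past the threshold, with a median of 0.78 and 28 when adjusted over the list alone. That list passed camera (adjusted p = 9.7e-36), with adjusted p = 0.0797 with an estimated correlation and a fry adjusted p of 0.00464. Glucocorticoid targets had a median interaction of 0.29 over 25 members, 5 of them positive when adjusted over the list alone (adjusted p = 0.519 with an estimated correlation), and Ddit4 (1.99, SE 0.496, adjusted p = 0.209) and Trim63 (0.79, SE 0.17, adjusted p = 0.145) did not pass.

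For the interaction 29 genes passed in limma, 24 positive and 5 negative. With the tendon score as a covariate 2 passed and 0 of the 34 interferon genes did, although their median was still 0.66 with a median SE of 0.172 (0.78 and 0.178 without it). Leaving out control animals 18 or 19 gave 8 or 50 genes, LCN13 animals 21, 22 or 23 gave 14, 11 or 17, TSC22D4 animals 25, 26 or 27 gave 5, 4 or 3, and TSC22D4+LCN13 animals 29 or 32 gave 10 or 15. Herc6 passed in each of the 12 fits that left out 1 array. Parp14 was lost in 1 (largest adjusted p = 0.0595, without TSC22D4 animal 27), and Ifit1, Cmpk2 and Irf7 in 3, 4 and 7, with largest adjusted p of 0.0707, 0.0712 and 0.086 without TSC22D4 animal 26. Camera called 10 of 48 lists, 8 positive and 2 negative, against 0 with an estimated correlation.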

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

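The tests of leukocyte content, of single control arrays and of virus dose in this part were chosen only after the result was seen.

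A difference between backgrounds marked these results: the change with TSC22D4 shRNA differed between animals with and without LCN13 shRNA for 29 genes and 10 gene lists, of which 0 passed with an estimated correlation (smallest adjusted p = 0.0797). On the log2 scale the interaction was 2.28 for Ifit1, 2.24 for Irf7, 2.18 for Cmpk2, 1.66 for Herc6, 1.66 for Ifit2, 1.40 for Phf11d, 1.36 for Oasl2, 1.33 for Parp14, 1.32 for H2-T24, 1.32 for Lgals9, 1.22 for Dtx3l and 1.21 for Rnf213. It was -0.33 for Kcnk15, -0.28 for Med13 and -0.27 for Tas1r1. Most of these calls were lost in most fits with 1 array left out. Over the 12 fits that left out 1 array, Ifit2, Oasl2, Dtx3l and Kcnk15 were each lost in 8. H2-T24 and Med13 were lost in 9, Phf11d, Lgals9 and Rnf213 in 10 and Tas1r1 in 11. The losses of Ifit1, Irf7, Cmpk2, Herc6 and Parp14 are given above. Of 100 splits drawn from the 12 arrays, the real one included, 1 gave as many genes (29, against at most 16 in the others). These splits ask whether the groups differ at all and do not test the interaction by itself. They therefore do not decide whether the interaction count arose by chance. The count was 5, 4 or 3 without TSC22D4 animals 25, 26 or 27 and 2 with the tendon score as a covariate. For the lists 52 of 100 splits gave as many as the real 10, with up to 18, and chance cannot be excluded.

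Median interactions of the lists were 0.78 for the interferon response, 0.29 for glucocorticoid targets, 0.22 for macrophages and monocytes, 0.14 for immediate early genes, 0.12 for FoxO targets, 0.12 for muscle atrophy and ubiquitin ligases, 0.11 for the proteasome and 0.032 for acute phase and NF-kB inflammation. They were -0.11 for fatty acid oxidation and PPAR targets and -0.086 for myokines and muscle-secreted factors.

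Behind the interaction, interferon genes stood higher in the 3 control arrays than in the other 9, by a median of 0.51 on the log2 scale. More leukocytes in the control muscles as a whole are argued against by the 24 leukocyte markers outside the list and above the median level, out of 72 measured, whose median difference was -0.066 (quartiles -0.202 and 0.032, 8 higher and 16 lower in control, against a median of -9e-04 with 36 higher and 36 lower over all 72, among the higher Ly6c2 at 0.526 and Igkc at 0.513, so that single cell types stay open), and 1 control array alone by the list's median change, which over the comparisons with control came no nearer to 0 than -0.427 when any control array was left out. A rise in proportion to the dose of control virus is argued against as well. The list score was -0.216 without that virus and -0.21 where it made up 1 of 2 equal parts of the dose. The step between them was 0.0063 of that up to the control score of 0.636. The -0.21 pools LCN13 shRNA at -0.269 and TSC22D4 shRNA at -0.151, which lay on either side of -0.216. A two-sided exact permutation test over 84 splits gave p = 0.881, which with so few arrays does not by itself show that no step exists. Single genes did fall further, such as Oasl2 by 0.71 from LCN13 to TSC22D4+LCN13 shRNA. What stays open is that the control virus or its preparation may raise interferon genes above some dose, or that either target virus may lower them with less than additive effect, and the design does not separate these because only control animals received control virus alone. An array batch that follows the groups stays open and was not tested.

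Among the 2021 probe sets without a single gene symbol, which no comparison of named genes used, 3 were higher than control with LCN13 shRNA (10 lower) and 15 were higher than control with TSC22D4+LCN13 shRNA (58 lower), against 0 higher and 1 lower with TSC22D4 shRNA.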

How the results depend on the processing

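The fits with the tendon score, with the hepatocyte score and without animals 22, 23 and 30 together were chosen only after the data were seen. Of 98 called values of named genes, 0 changed sign under any alternative, 37 kept their call in each fit that left out 1 array and 61 lost it in at least 1. The call was lost for 53 of 98 with the tendon score and for 63 of 83 with the compared groups alone. With the average effect over both backgrounds, 6 arrays against 6, it was lost for 29 of 40. The mean of a gene's probe sets gave identical values because every gene has 1 probe set, and quantile normalization and median centring changed little because the deposited distributions were already equal. No paired analysis was possible because the groups share no animal numbers. Genes near the floor of the arrays, such as Obp2a, carry little signal over background.

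For TSC22D4 shRNA against control (78 genes), array weights gave 177, the 2 groups alone 33, the average effect over 6 against 6 arrays 542 and the tendon score 25, and leaving out 1 array gave 36 to 105. For LCN13 shRNA against control (197 genes) the same 4 gave 340, 18, 14 and 20, the data without animals 22, 23 and 30 gave 412, and leaving out 1 array gave 77 to 280. For TSC22D4+LCN13 shRNA against control (1007 genes), the 2 groups alone gave 124, the tendon score 34, and leaving out 1 array 334 to 1106. For TSC22D4+LCN13 against TSC22D4 shRNA (0 genes by limma, 2434 of 23185 at an unadjusted p under 0.05), the hepatocyte score gave 2, and leaving out 1 array 0 to 2. For TSC22D4+LCN13 against LCN13 shRNA (977 genes), array weights gave 543, the 2 groups alone 0, and leaving out 1 array 318 to 1320. For the interaction (29 genes), genes above the median level gave 51, the tendon score 2, the data without animals 22, 23 and 30 gave 76, and leaving out 1 array 3 to 50. The 2-group and left-out fits hold fewer arrays, and for the other settings the cause was not tested.

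Gene lists past the threshold numbered 14, 13, 10, 14, 6 and 10 over the 6 comparisons in this order. They were 0, 1, 0, 0, 0 and 0 with an estimated correlation and 2, 1, 3, 0, 0 and 1 by fry. With genes above the median level they were 9 for TSC22D4 shRNA against control and 2 for TSC22D4+LCN13 against LCN13 shRNA. With the tendon score, whose 6 genes all belong to the list of fibroblasts and tendon cells, so that its loss is built in, they were 8 for LCN13 shRNA against control and 3 for TSC22D4+LCN13 shRNA against control, and for the latter 6 with the hepatocyte score. Without animals 22, 23 and 30 the LCN13 shRNA group held animal 21 alone, so lists past the threshold are not counted there. With 1 array left out they ranged from 9 to 15 for TSC22D4 shRNA against control, from 5 to 17 for TSC22D4+LCN13 shRNA against control, from 3 to 20 against TSC22D4 shRNA and from 3 to 9 against LCN13 shRNA. The cause was not tested.

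Sign changes fell on values that were not called. Obp2a turned to -0.011 with the tendon score for TSC22D4 shRNA against control, to 0.0032 with the hepatocyte score and 0.0039 without animals 22, 23 and 30 for LCN13 shRNA against control, to -0.018 with the tendon score for TSC22D4+LCN13 shRNA against control, to -0.0069 with the tendon score for TSC22D4+LCN13 against TSC22D4 shRNA, and to -8e-04 without animals 22, 23 and 30 for the interaction. With 1 array left out Obp2a ranged from -0.013 to 0.023, from -0.016 to 0.0098, from -0.0074 to 0.025, from -0.014 to 0.021, from -2e-04 to 0.029 and from -0.0082 to 0.028 over the 6 comparisons. For LCN13 shRNA against control Alb turned to -0.10 with the hepatocyte score, which holds Alb itself, and Mup3 to -0.12 without animals 22, 23 and 30. Tsc22d4 in TSC22D4+LCN13 against TSC22D4 shRNA turned to 0.078 with the tendon score and 0.035 without those animals, and ranged from -0.11 to 0.042 with 1 array left out. Against LCN13 shRNA it turned to -0.0042 with quantile normalization, -0.002 with median centring and -4e-04 with array weights, and ranged from -0.097 to 0.097. The cause was not tested.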

Other observations

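In this part, the count of LCN13 shRNA arrays above the controls in hepatocyte score, the fits with the tendon or hepatocyte score and the fit without animals 22, 23 and 30 were chosen only after the result was seen.

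Gene families close to the study's targets held no gene past the threshold against control in limma. The TSC22 family and its partners, 8 genes measured, had median log2 changes against control of -0.055 with TSC22D4 shRNA, -0.032 with LCN13 shRNA and -0.058 with both, with camera adjusted p of 0.657, 0.903 and 0.561. Lipocalins, 15 genes measured, had medians of -0.0027, -0.0072 and -0.017, with camera adjusted p of 0.61, 0.944 and 0.249. Members went both ways, as Lcn2 at 0.62 (adjusted p = 0.304) and Apod at -0.41 (adjusted p = 0.31) with LCN13 shRNA, and did not pass.

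Hepatocyte transcripts stood high in LCN13 animals 22 and 23 and TSC22D4+LCN13 animal 30, with list scores of 0.873, 0.35 and 0.507 against at most -0.001 in the control arrays. Liver RNA carried into these samples is a candidate explanation. The deviations of the 22 list members followed the same profile in the 3 arrays, with a lowest correlation across genes of 0.828 (genes are not independent replicates). The arrays were picked by this list's score and their deviations share a reference, so the correlation does not tell between causes. Alb reached 11.6, 10.9 and 10.9 in these arrays, but also 10.1 in control animal 19. An effect of LCN13 shRNA on muscle in part of the animals cannot be told apart from liver RNA. Of the 6 arrays with LCN13 shRNA 3 lay above the highest control array, and these same animals defined the pattern.

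Extracellular matrix genes stood higher with TSC22D4+LCN13 shRNA than in control by a median of 0.54. A single array is argued against as the whole source, since the median kept at least 0.732 of its size whichever of the 6 arrays was left out (0.39 without animal 30). That does not test pairs of arrays, and the groups overlapped. The list score was -0.561, -0.048 and -0.375 in control animals 18, 19 and 20. It was -0.148, 0.467 and 0.317 in TSC22D4+LCN13 animals 29, 30 and 32. Tendon content of the sample is a candidate explanation: with a score of 6 tendon genes outside the list as a covariate the median fell to 0.11, which is 0.203 of its size. The covariate also differs between the groups, so it may remove part of a change of matrix genes in muscle itself, which stays open.

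For the other comparisons, 3 arrays against 3 give 10 splits, too few for a share under 0.05. In counts of genes, TSC22D4 shRNA against control gave 78 and at most 1 in another split, LCN13 shRNA against control 197 and at most 0, TSC22D4+LCN13 shRNA against control 1007 and at most 0, and TSC22D4+LCN13 against LCN13 shRNA 977 and at most 0, so that in each 1 of 10 splits, the real one, gave as many. TSC22D4+LCN13 against TSC22D4 shRNA gave 0 genes by limma in 10 of 10 splits, with 2434 of 23185 genes at an unadjusted p under 0.05 in the real one. In counts of lists, TSC22D4 shRNA against control gave 14 and at most 13 elsewhere (1 of 10 splits as many), and LCN13 shRNA against control 13 and at most 11 (1 of 10). TSC22D4+LCN13 shRNA gave 10 against control and at most 15 elsewhere (7 of 10), 14 against TSC22D4 shRNA and at most 20 (4 of 10), and 6 against LCN13 shRNA and at most 20 (10 of 10).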
